A study of Paralichthys olivaceus with 2 samples.

How the data were processed

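The study hybridised 2 single-colour miRNA arrays, 1 with RNA of larvae at 17 dph and 1 at 29 dph. Per the labels' protocols, total RNA from 5 whole larvae was extracted with Trizol, small RNAs were isolated by size filtration, extended with a poly(A) tail and joined to an oligonucleotide tag for staining, here with Cy5. The tail and tag add every small RNA in the fraction to the labelled pool, fragments of longer RNAs included. Each deposited array table gives 1 mean density per spot, which is a linear intensity without background subtraction or scaling between the arrays, as judged from the values. It has 3968 spots, of which 2961 belong to 987 probes, 715 are empty and the rest are calibration or 5S rRNA control spots. The scanner and image software are not given in the sources used here. The authors' series table gives 1 processed intensity per probe, with medians of 37.1 at 17 dph and 41.0 at 29 dph. It follows the scanner densities with rank correlations of 0.991 and 0.998. Its scale is linear and its direction follows the arrays, while the authors' background and scaling steps stay unknown.

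Spot densities were background-corrected with limma 3.58.1 in R 4.3.3 (normexp on all spots, offset 50), log2-transformed, quantile-normalized between the 2 arrays over the probe spots, and averaged over the 3 spots of a probe. Control spots were left out after the background step. Quantile normalization gives both arrays the same distribution over all probes, candidates included, so an overall difference between stages is removed. Of the 987 probes, 544 were PC-coded candidates, with a median density of 74.5 at 17 dph and 352.1 at 29 dph. The conserved probes had medians of 45.9 and 45.1. The common scale therefore rests largely on candidates, and none of the scalings run here used conserved probes alone. Probes of conserved miRNAs with the same mature name were averaged. Where several probes of a detected name were compared, their log2 differences had opposite signs for 4 of 7 names (let-7j, miR-15b, miR-216a and miR-30c).

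A probe was detected when at least 50% of its spots lay above the mean + 3 SD of the array's empty spots, and a miRNA when any of its probes was. The median spot CV of detected probes was 8.06% at 17 dph and 6.49% at 29 dph. A miRNA was called higher or lower at 29 dph when it was detected on at least 1 array, its log2 difference (29 dph minus 17 dph) was at least 1 in size and the spot ranges of the 2 arrays did not overlap. With 1 array per stage no p-value was computed. For a miRNA detected on 1 array only, the fold is a lower bound, the bright array's mean normalized log2 signal against the higher of the lowest signal among detected probes on the dim array and the miRNA's own.

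Members of the 15 miRNA lists were matched by miRNA number, passenger strands left out. Random lists were drawn 10000 times from the 126 detected miRNAs, with each member replaced by one of the 21 nearest in mean signal. Correlations are Spearman's rho with 95% intervals from 10000 bootstrap draws. Values were computed with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1. Named miRNAs were chosen by rule: up to 15 of the most positive and 15 of the most negative among those called and detected on both arrays, up to 5 in each direction detected on 1 array only, the 10 brightest of each array, and in each list the member with the largest difference and the brightest. The comparison, this rule, the lists and most alternatives were set before the data were examined. In a list, the brightest member was taken as the one with the largest sum of densities over the 2 arrays.

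The calls were tested on simulated arrays with the 987 probes. Of 100 probes changed by a log2 size of 1.5, 89 were called in the true direction, and of 100 changed by 3 all 100 were. Of 485 unchanged detected probes 0 were called. Of 200 simulated unchanged lists of 10 probes, 10 fell in the outer 5% of random lists, and all 200 did so on the low side after being lowered by a log2 size of 1. The simulation held spot noise only, not the variation between larvae, RNA preparations or arrays. Changed probes were drawn from those with a mean signal over 100 above background, with equal numbers raised and lowered. Unchanged probes took the same quantile on both arrays, which favours quantile normalization. The simulation therefore gives no error rate for dim miRNAs, for unbalanced changes or for differences that follow GC content.

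Alternatives were no normalization, scaling to the median or the 75th percentile of the probes detected on both arrays, cyclic loess, plain background subtraction with a floor of 1, no background correction, the authors' series table, the median of the spots, other filters on dim probes, thresholds of 1.5-fold and 4-fold, no condition on the spots, and other detection limits. A further pair, a detection limit from the median and MAD of the empty spots and removal of the GC trend, were added after the data were seen. Genomic positions of the miRNA genes were not analysed here, since the gene table used lists no miRNA genes. Candidate probes were left out of the comparison because the meaning of their codes is not stated.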

Results

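The abundance of microRNAs (miRNAs, short RNAs that repress target mRNAs) was measured in whole larvae of the Japanese flounder (Paralichthys olivaceus), a flatfish whose larva turns from a symmetric swimmer into an asymmetric bottom dweller. One array held RNA from 17 days post hatching (dph), a stage the labels call pre-metamorphic, and one array held RNA from 29 dph, called mid-metamorphic. Each RNA came from a tube of 5 larvae. With 1 array per stage, no difference below has a replicate check and no test between stages was possible. SD values are over the 3 spots of a probe and cover only the technical spread within an array.

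Each array carried 987 probes in 3 spots. Of these, 263 probes matched known miRNAs of zebrafish or pufferfish, which made 252 mature miRNA names once the species prefix was removed. The other probes were 544 candidates with PC codes and 180 with PN codes. The median density of the probe spots was 55.4 at 17 dph and 139.4 at 29 dph, against medians of 45.6 and 38.8 in 715 empty spots. The probe spots were therefore brighter at 29 dph, while the empty spots were not. Conserved probes, detected or not, had medians of 45.9 and 45.1, and most calibration probes bright on both arrays were dimmer at 29 dph. The number of arrays limits the precision of every value.

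The first question was which conserved miRNAs could be detected at each stage. At 17 dph 66 mature miRNAs lay above the detection limit, and at 29 dph 126 did. The 66 were all among the 126, and the conserved probes of 60 miRNAs were detected at 29 dph only. For 8 of the 60 (miR-145, miR-19b, miR-200a, miR-204, miR-2188, miR-30d, miR-7 and miR-7a), a nested candidate probe was above the limit at 17 dph. Its target lay within that of the conserved probe or contained it, and miR-7 and miR-7a shared the same candidate. The detection limit was a density of 68.7 on the 17 dph array, where 2 of the empty spots were brighter than 100, and 45.6 on the 29 dph array.

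The brightest miRNA at 17 dph was miR-214, with a density of 1968 ± 135 (SD over 3 spots). It was followed by miR-206, a skeletal muscle miRNA, at 1653 ± 52.0 and by miR-21 at 1248 ± 66.1. The other members of the 10 brightest were miR-181a, miR-22a, miR-26a, miR-92a, the liver miRNA miR-122, the gut miRNA miR-192 and miR-125a. At 29 dph miR-206 was the brightest, at 10711 ± 254, and miR-1, a miRNA of skeletal and heart muscle, came next at 7729 ± 431. These were followed by miR-192 at 6769 ± 481, miR-21 at 6329 ± 250, miR-26a at 5513 ± 16.8 and miR-122 at 5269 ± 207.9. miR-214, miR-199*, the skin miRNA miR-203a and miR-22a completed the 10. Names miR-206, miR-21, miR-22a, miR-26a, miR-122, miR-192 and miR-214, stood in both groups. Ranks within an array compare different probes, whose binding differs.

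The main comparison asked which conserved miRNAs differed between 17 and 29 dph. After quantile normalization 11 mature miRNAs were higher at 29 dph by a log2 difference of at least 1 with spot ranges that did not overlap. A further 22 were lower, and 93 of the 126 detected miRNAs were neither. The muscle miRNA miR-1 had the largest difference, and miR-92a, a member of the miR-17-92 clusters linked to cell proliferation, was the lowest. The median log2 difference of the 126 detected miRNAs was -0.29. Directions depended on the scaling. With no scaling between the arrays the median was 1.07, with 64 miRNAs higher and 1, miR-92a, lower, while scaling to the median of the probes detected on both arrays gave a median of -1.35, 6 higher and 83 lower. A lower value at 29 dph therefore means lower relative to the other probes, and the differences of single miRNAs are best read against these medians.

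**Figure D1:**
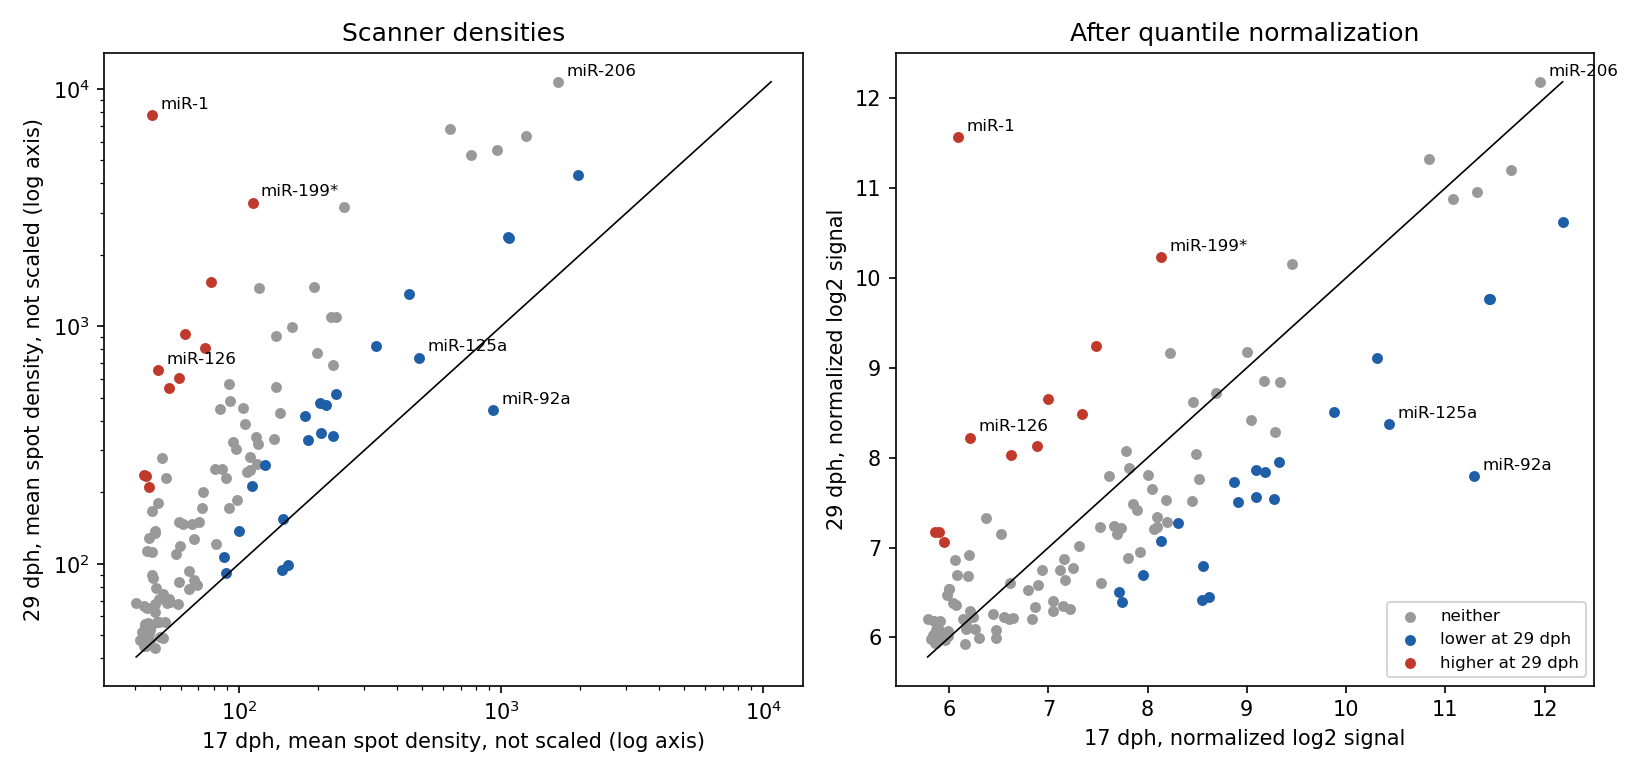
The 126 mature miRNAs detected on at least 1 array, 1 point each, with 17 dph on the x axis and 29 dph on the y axis. The left panel plots mean spot densities on log axes and the right panel normalized log2 signals, and the line marks equal values. Of the 22 miRNAs in blue (lower after quantile normalization), 19 had a positive difference without scaling, and miR-1, in red (higher), lies far above the line in both panels.

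Among the miRNAs detected on both arrays, 3 were higher at 29 dph. miR-199*, from a precursor expressed in connective tissue, had a log2 difference of 2.10, with normalized log2 signals of 8.14 ± 0.20 at 17 dph and 10.23 ± 0.043 at 29 dph. The other strand, miR-199, did not share this direction, with a difference of -0.62 (neither higher nor lower) and -0.71 by a nested candidate probe. miR-26b had a difference of 1.76 and miR-203b, related to the skin miRNA miR-203a, one of 1.14. Their densities at 17 dph, 78.4 and 73.9, were close to the detection limit of 68.7. These 3 higher miRNAs were positive under all 8 ways of scaling and background correction that were compared, with differences of 1.83 to 4.71 for miR-199*, 1.17 to 4.05 for miR-26b and 0.34 to 3.23 for miR-203b, which was called in 5 of the 8. The brighter miR-26a, with a nearly identical target to that of miR-26b, had a difference of -0.37. Its density at 29 dph was 5513, against 1532 for miR-26b. The probe for miR-199* targeted UACAGUAGUCUGCACAUUGGUU.

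The remaining 8 higher miRNAs were above the detection limit at 29 dph only, so that each has a lower bound. miR-1 was at least 21.9-fold higher at 29 dph. Its target sequence was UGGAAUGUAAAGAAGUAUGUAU, and its density was 46.7 ± 4.2 at 17 dph, close to the median of empty spots. miR-16b was at least 2.89-fold higher, the endothelial miRNA miR-126 at least 2.15-fold, and the epithelial miRNAs miR-200b and miR-200c at least 2.02-fold and 1.88-fold. These bounds moved with the scaling. With scaling to the 75th percentile of the probes detected on both arrays they were 12.9-fold for miR-1, 1.57-fold for miR-16b, 1.12-fold for miR-126 and 1.04-fold for miR-200b, miR-200c had none above 1, and only miR-1 of these kept its call. The bounds for let-7f and let-7g were close to 1, at 1.04-fold each, and miR-16a had none above 1. These last 3 were named after their values were seen, and for all 3 the direction turned when the arrays were scaled to the median or the 75th percentile of the probes detected on both.

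All 22 lower miRNAs were detected on both arrays. The lowest was miR-92a, with a target of UAUUGCACUUGUCCCGGCCUGU. Its log2 difference was -3.50 and its density 934 ± 142 at 17 dph and 444 ± 38.8 at 29 dph. It was followed by miR-19d at -2.17 and miR-92b at -2.13. These 3 were negative in all 8 ways of scaling, from -4.14 to -1.03 for miR-92a, but with the GC trend removed miR-92b stood at -0.38 and was no longer called. The other lower miRNAs all turned positive with no scaling between the arrays. They included miR-125a at -2.06, the neuronal miRNA miR-124 at -1.77, miR-10d, encoded in a Hox cluster, at -1.74, miR-181a at -1.68, miR-22a at -1.67, miR-214 at -1.56, miR-20b at -1.53 and miR-222 at -1.40. miR-17a at -1.38, miR-25 at -1.37, the muscle miRNA miR-133a at -1.34 and miR-132 at -1.34 followed.

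The differences were lower for targets of higher GC content. Of the 11 higher miRNAs, 10 had a target GC content under 45%, and of the 22 lower miRNAs 20 had one of 45% or more. Across the 126 detected miRNAs Spearman's rho between GC content and log2 difference was -0.66 (95% bootstrap interval -0.75 to -0.54), although 60 of these were at background at 17 dph. Over the 66 detected on both arrays it was -0.55 (interval -0.71 to -0.35). This relation is across miRNAs, which are not independent replicates. It was 1 of 15 rank relations computed. Without scaling it was -0.14 (interval -0.32 to 0.039) over the 126 and -0.43 (interval -0.63 to -0.19) over the 66. With the linear GC trend removed, an alternative chosen after the data were seen, 7 miRNAs were higher and 13 lower, and of the original calls 6 of 11 and 8 of 22 were kept. miR-1, miR-199*, miR-92a and miR-19d were among those kept, whereas miR-26b, at 0.93, was not, and miR-214 moved from -1.56 to 0.023.

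**Figure D2:**
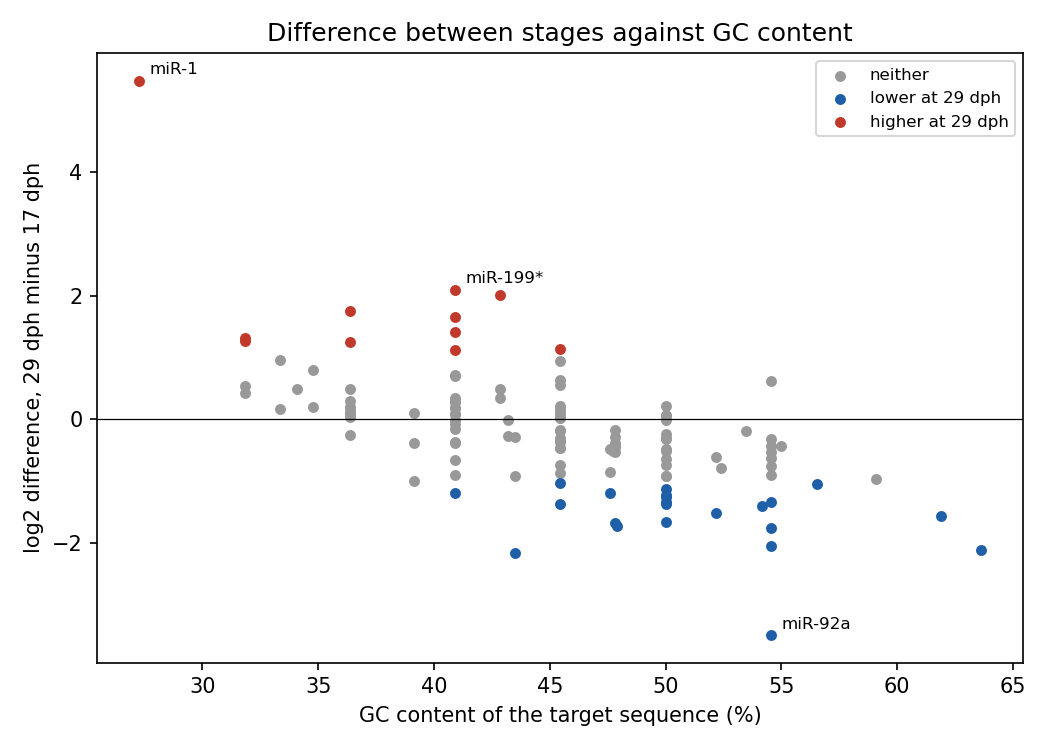
Log2 difference between 29 and 17 dph (y axis) against the GC content of the target in percent (x axis) for the 126 detected mature miRNAs, 1 point each. The median difference was 0.24 for the 24 miRNAs under 40% GC and -0.78 for the 40 miRNAs at 50% or more.

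A further question was whether miRNAs of a common family or tissue lay to one side. The 15 lists examined were fixed before the data were examined, and each list's median was set against 10000 random lists of the same size matched on mean signal, as a description of these 2 arrays. Random lists were drawn without regard to sequence, whereas family members such as miR-17a and miR-20b or miR-200b and miR-200c have similar targets. Such members are not independent, so the percentiles may overstate how unusual a list is. Members at background at 17 dph entered the medians with their measured differences. With these members at their bounds, or at 0 where there was none, the medians of the let-7, muscle, nervous system and miR-15/16 lists were 0, against 0.17, -0.073, -0.016 and 0.083 as measured. They were then -0.099 for liver, gut and pancreas and -0.28 for the broadly expressed list, against -0.26 and -0.37, and did not move for the miR-17-92 and cartilage lists. The miR-17-92 clusters and their relatives stood lowest. Of 10 detected members 7 were lower, 0 higher and 3 neither, and with the GC trend removed 4 of the 7 were still called lower. The list's median log2 difference was -1.37, or -1.09 relative to the median of all detected miRNAs, at percentile 0.05 of the random lists. miR-92a was its brightest member at 17 dph and the one furthest from 0. At 29 dph miR-17a was the brightest, with a density of 829 against 444 for miR-92a. The relative median was negative under every alternative run, although the list's own median was 0.23 with no scaling. Without miR-92a and miR-92b the relative median of the other 8 members was -1.001, at percentile 0.52.

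The epithelial list (miR-141, miR-200, miR-203, miR-205 and miR-429) stood highest by its conserved probes. Of 8 detected members 3 were higher, 0 lower and 5 neither, with a relative median of 0.81 at percentile 99.8. miR-200c was at least 1.88-fold higher, and miR-203a, the brightest member, had a difference of 0.70. The relative median was positive under every alternative run, and with the GC trend removed it was 0.45, at percentile 95.1. The 3 calls, for miR-200b, miR-200c and miR-203b, were lost with cyclic loess and with scaling to the median or the 75th percentile. With the conserved probes of 4 of the 8 members at background at 17 dph, the list's own median was 0.52 as measured and 0.35 with these at their bounds. Nested candidate probes above the limit on both arrays gave the opposite sign for miR-203a, at -0.12 against 0.70. They did so too for miR-200a, at -0.68 against 0.35, where the conserved probe was below the limit at 17 dph. For miR-141 the sign was the same, at -0.13 against -0.365, by a candidate probe that is also nested in miR-200a. These second-probe values all lay above -0.893, the median of 32 second probes over the limit at 17 dph, members of the lowest-standing list left out.

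In the muscle list 1 of 6 detected members was higher, 2 were lower and 3 were neither, and the list's relative median was 0.21 at percentile 78.6. miR-1 and miR-133a lay on opposite sides, with miR-1 at least 21.9-fold higher and miR-133a at -1.34, which became 1.08 without scaling. miR-206 had a difference of 0.22, which turned to -0.47 with cyclic loess. The relative median turned to -0.20 with cyclic loess and to -0.16 with the GC trend removed.

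The let-7 and developmental timing list (let-7, miR-98, miR-99, miR-100 and miR-125) had 15 detected members, of which 2 were higher, 3 lower and 10 neither. Its relative median was 0.46, at percentile 98.3. Its members differed among themselves, since let-7d, the brightest at 29 dph, had a difference of 0.17 and miR-125a, the brightest at 17 dph, one of -2.06 (0.59 without scaling). With the GC trend removed the relative median was 0.010, at percentile 64.1.

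The miR-15/16 family had 5 detected members, 2 higher, 0 lower and 3 neither. Its brightest member was miR-15a at 17 dph, with a density of 117.7, and miR-16b at 29 dph, with one of 928. Its relative median was 0.37, at percentile 76.6. The nervous system list had 9 detected members, 0 higher, 2 lower and 7 neither. Its relative median was 0.27, at percentile 62.9, and turned to -0.78 without scaling or with scaling by a single factor and to -0.21 with the GC trend removed. Its brightest member at 17 dph was miR-124, at -1.77 (0.070 without scaling). At 29 dph miR-218a was the brightest, with a density of 179.5 against 153.8 for miR-124. The Hox cluster list had 4 detected members, 0 higher, 1 (miR-10d) lower and 3 neither, with a relative median of -0.24 at percentile 17.9. With 2 of the 4 at background at 17 dph, its own median was -0.52 as measured and -0.15 with these at their bounds, and without a filter on dim probes the relative median was -0.031.

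Of 4 detected members of the cartilage, fibroblast and smooth muscle list, 1 (miR-214) was lower and 3 were neither. Its relative median was -0.45, at percentile 37.1, and turned to 0.040 without scaling and to 0.27 with the GC trend removed. Names with a star were left out of this list as passenger strands. Of these, miR-140* was lower at -1.06, while miR-140 was not detected, and miR-199* was higher at 2.10. The liver, gut and pancreas list had 6 detected members, 0 higher, 1 lower and 5 neither, and a relative median of 0.031 at percentile 55.6, which turned to -0.054 with cyclic loess and to -0.28 in the authors' table. Its lower member was miR-194a at -1.20 (1.59 without scaling), while miR-192 had a difference of 0.49 and miR-122 one of -0.20. Of 21 detected members of the broadly expressed list, 1 (miR-26b) was higher, 3 lower and 17 neither. Its relative median was -0.080, at percentile 16.3, and turned to 0.062 without scaling.

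Lists with fewer than 3 detected members have no percentile. Of the sensory organ miRNAs 2 of 3 were detected, and miR-182 had a difference of -0.66 and miR-183 one of -0.92. For eye and pigment 2 of 3 were detected, with miR-184 at -0.19 and miR-204 with a density of 112.7 at 29 dph. The conserved probe of miR-204 was below the limit at 17 dph, whereas a nested candidate probe was above it on both arrays, with densities of 139.2 and 549.5. For blood and immune cells 2 of 8 were detected, at 29 dph only, with densities of 51.7 for miR-451 and 55.8 for miR-150. All 6 were neither higher nor lower. The endothelial list had miR-126 as its 1 detected name of 2, and 0 of the 5 miR-430 names of the early embryo were detected on either array.

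**Figure D3:**
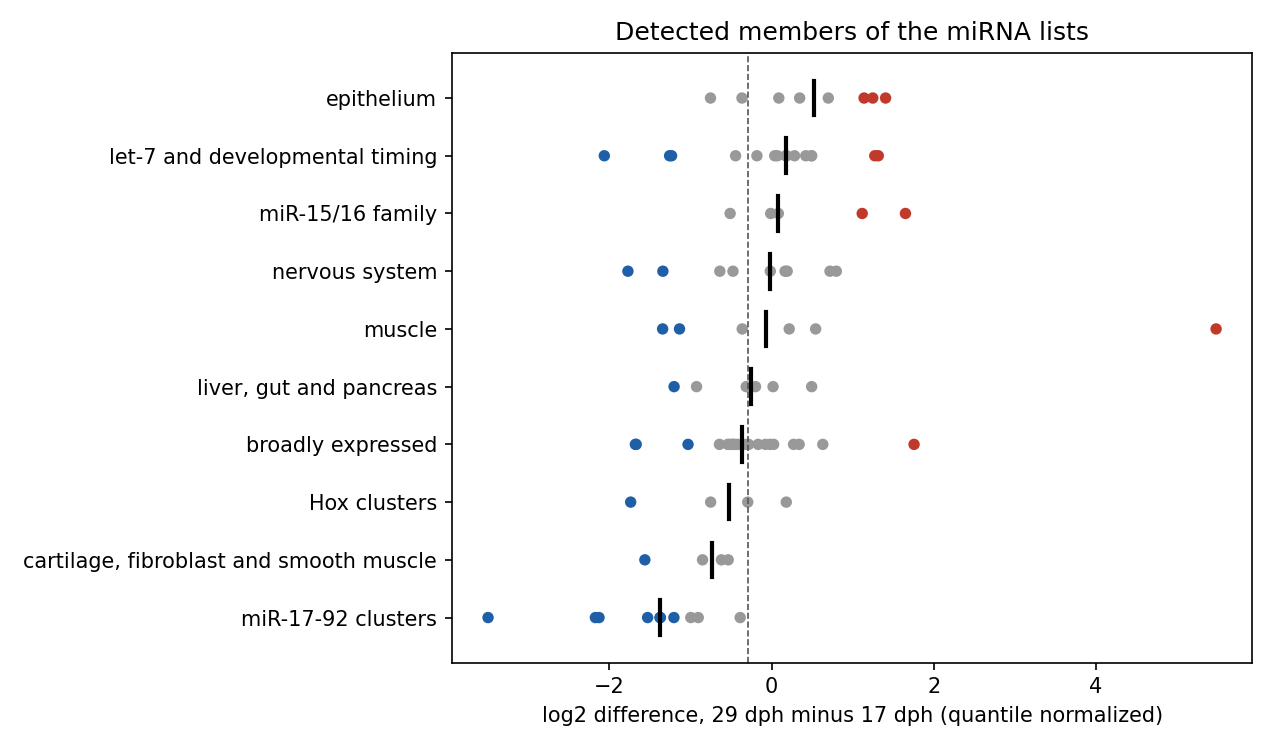
Log2 difference between 29 and 17 dph (x axis) of each detected member of the 10 miRNA lists with at least 3 detected members (y axis), with red for higher, blue for lower and grey for neither. Black bars mark each list's median and the dashed line the median of all 126 detected miRNAs, -0.29. The miR-17-92 list lies furthest left relative to that line and the epithelial list furthest right, and both kept their side of the median of all detected miRNAs under every scaling, whereas the nervous system, cartilage and broadly expressed lists changed sides without scaling and the muscle and liver lists with cyclic loess.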

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

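All tests of explanations in this part were chosen after the results were seen. The candidate probes and control spots, which entered the processing but not the comparison of conserved miRNAs, held signal. Of the PC-coded probes 446 of 544 and of the PN-coded probes 110 of 180 lay above the detection limit at 29 dph. Of the overlapping sets of PC-coded probes, the brightest at 17 dph, 10 probes whose targets span 24 nt, had a median density of 47436 at 17 dph and 28146 at 29 dph. The brightest at 29 dph, 4 probes that span 23 nt, had one of 27752 at 17 dph and 52513 at 29 dph. The calibration probe PUC2PM-20B was 3.21 times as bright at 29 dph as at 17 dph, whereas PUC2PM was 0.643 times as bright. All 3 bright calibration probes with 20B in their name were brighter at 29 dph, and the other 7 calibration probes over a density of 100 on both arrays were dimmer.

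The first pattern weighed is the lower difference of miRNAs with GC-rich targets, which without scaling was clear only among miRNAs detected on both arrays. Compression of dim probes would leave little relation among bright ones, but over 32 miRNAs more than 2 times the detection limit at 17 dph rho was -0.56 (95% bootstrap interval -0.79 to -0.21). A few large families would end it at 1 value per miRNA number, which stays unsettled, since rho was -0.46 (interval -0.68 to -0.19) over 46 numbers detected on both arrays and -0.58 over 76 with those at background at 17 dph. Weaker binding of low-melting targets on the 17 dph array stays open too: over 60 pairs of probes nested in the same miRNA, the lower-melting probe tended to have the more positive difference, with a rho of -0.53 (interval -0.70 to -0.31), and of -0.44 over the 30 pairs with both probes above the limit at 17 dph. If both probes of a pair read the same miRNA, they share its abundance, and this relation may be technical. Some candidates nest with 2 conserved miRNAs, such as PN182 with let-7a and let-7c, so a pair need not read 1 abundance. Neither this nor a real difference between stages was tested.

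The second pattern is miR-1, at background at 17 dph and bright at 29 dph. Low GC content would place it on the trend of the other miRNAs, but its lower bound, a log2 difference of 4.45, lay 4.32 residual SD above the trend of the 66 detected on both arrays (1.12 when extended from their lowest GC content, 36.4%, to 27.3%). Binding of miR-206 in a constant share would give the same ratio on both arrays, but the miR-1 signal above background was at most 1.44% of that of miR-206 at 17 dph, with miR-1 set at the detection limit, and 72.1% at 29 dph. A fault of 1 probe would spare a second one, but a second probe nested in the miR-1 sequence was likewise below the detection limit at 17 dph and was at least 9.02-fold higher at 29 dph, a log2 difference of at least 3.17. A higher level of miR-1 at the later stage is thus a hypothesis, and differences between the 2 tubes of larvae or their RNA stay open with 1 array per stage.

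The third pattern is the low position of the miR-17-92 clusters. GC content is argued against, since with the GC trend removed the list stood at percentile 0 of the 10000 random lists, with a relative median of -1.09, although only 4 of its 7 lower calls were left. A fault of the miR-92a probe is argued against as well, since 3 second probes nested in its sequence were all called lower, the highest at -2.59. For the other members faults of single probes stay open: second probes exist for 4 of the 9, with log2 differences of -1.55 for miR-93, -1.525 for miR-19b, -0.54 for miR-20a and 0.18 for miR-25 (below the limit at 17 dph), and their median minus that of 53 second probes of other miRNAs was -0.677. Differences between the 2 RNA samples other than stage stay open, and stage itself was not tested.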

How the results depend on the processing

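Signal over background was low at 17 dph, where the median probe spot stood at 55.4 against 45.6 for empty spots. No paired analysis was possible because each stage had 1 array. The numbers detected stayed within 1.5 times, at 51 to 78 miRNAs at 17 dph and 113 to 135 at 29 dph over 5 other limits or ways of counting. The 11 higher and 22 lower calls became 64 and 1 without scaling between the arrays (98.5% of calls higher, against 33.3%), 6 and 83 with scaling to the median of the probes detected on both arrays (6.7%), and 3 and 95 with scaling to their 75th percentile (3.1%). They became 5 and 23 with cyclic loess (17.9%), 30 and 43 with plain subtraction, and 23 and 48 in the authors' table, where no spots allowed a spot condition. By construction, thresholds of 1.5-fold and 4-fold gave 18 and 39 or 3 and 4, and 3 higher calls were left when detection on both arrays was required. Removing the GC trend, an alternative added after the data were seen, left 7 and 13. The counts stayed within 1.5 times without background correction, with the median of the spots, without a filter, without the spot condition and with the median + 3 MAD limit, also added later. Among named miRNAs called higher or lower, signs turned without scaling for miR-10d (0.58), miR-124 (0.070), miR-125a (0.59), miR-132 (0.045), miR-133a (1.08), miR-17a (1.28), miR-181a (1.13), miR-194a (1.59), miR-20b (0.76), miR-214 (1.13), miR-222 (0.82), miR-22a (1.15) and miR-25 (1.11), and with the GC trend removed for miR-214 (0.023). Of the 13 named miRNAs not called, signs turned for 6 without scaling (miR-21, miR-26a, miR-122, miR-182, miR-183 and miR-184), for 5 each with scaling to the median or the 75th percentile, for 3 with the GC trend removed and for 1, miR-206, with cyclic loess and in the authors' table. The median of all detected miRNAs moved with them, from -0.29 to 1.07 without scaling, -1.35 and -1.81 with scaling to the median and the 75th percentile, -0.17 with cyclic loess, -0.49 with plain subtraction, -0.31 without background correction and -0.59 in the authors' table. Of the calls, miR-1, miR-199* and miR-26b (higher) and miR-92a (lower) were made under all 8 ways of scaling and background correction. List values are medians relative to all detected miRNAs, so scaling by a single factor gives the value without scaling. For muscle it moved from 0.21 to 0.055 without scaling, -0.20 with cyclic loess, 0.029 in the authors' table, -0.43 on both arrays, -0.011 without a filter and -0.16 with the GC trend removed. For let-7 and developmental timing it moved from 0.46 to 0.83 without scaling, 0.23 with cyclic loess, 0.69 with plain subtraction, 0.65 in the authors' table, 0.74 on both arrays, 0.24 without a filter and 0.010 with the GC trend removed. For miR-17-92 clusters it moved from -1.09 to -0.83 without scaling, -1.28 with cyclic loess, -1.75 with plain subtraction, -1.495 in the authors' table, -0.67 on both arrays and -0.94 without a filter. For nervous system it moved from 0.27 to -0.78 without scaling, 0.54 with plain subtraction, -0.64 on both arrays, -0.032 without a filter and -0.21 with the GC trend removed. For epithelium it moved from 0.81 to 1.27 without scaling, 1.79 with plain subtraction, 1.64 in the authors' table, 0.41 without a filter and 0.45 with the GC trend removed. For liver, gut and pancreas it moved from 0.031 to 0.16 without scaling, -0.054 with cyclic loess, -0.28 in the authors' table, 0.14 on both arrays and -0.17 without a filter. For cartilage, fibroblast and smooth muscle it moved from -0.45 to 0.040 without scaling, -0.64 with cyclic loess, -0.83 with plain subtraction, -0.66 in the authors' table, -0.15 on both arrays, -0.56 without a filter and 0.27 with the GC trend removed. For Hox clusters it moved from -0.24 to -0.64 without scaling, -0.82 with plain subtraction and -0.59 in the authors' table, and within the spread between spots to -0.45 with the GC trend removed and -0.39 with the median of the spots. For miR-15/16 family it moved from 0.37 to 0.035 without scaling, 0.25 with cyclic loess, 1.41 with plain subtraction, 0.43 without background correction, 1.20 in the authors' table, 0.085 without a filter and 0.038 with the GC trend removed. For broadly expressed it moved from -0.080 to 0.062 without scaling, -0.22 with cyclic loess, 0.10 with plain subtraction, 0.24 on both arrays, -0.22 without a filter and 0.050 with the GC trend removed. The cause of these list shifts was not tested. Hox clusters and the miR-15/16 family had too few members detected on both arrays for a value there, and miRNAs detected on 1 array had none. Every alternative listed before the data were examined was run.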

Other observations

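The test of a hypothesis in this part was chosen after the data were seen. Many PN-coded candidates had targets nested with those of conserved miRNAs, 83 of the 86 candidates so nested, and so gave second measurements. Some of them, such as PN182 with let-7a and let-7c, nest with 2 conserved miRNAs and are not specific to 1. Over 60 such pairs with both probes detected, covering 53 miRNAs, 48 pairs had differences of the same sign, and rho between the probes was 0.78 (95% bootstrap interval 0.62 to 0.88, across probes, which are not independent replicates). Of 16 pairs whose conserved probe was called higher or lower, 15 had the same sign and 11 the same call. miR-126, miR-199*, miR-200b, miR-124, miR-133a and miR-214 had second probes with log2 differences of 1.35, 2.64, 1.33, -1.60, -1.62 and -1.57, of which those of the first 3 were below the detection limit at 17 dph. The second probes of miR-92a lay between -3.31 and -2.59. The 17 nt second probe of miR-25 had 0.18 against -1.37, and one of 2 second probes of miR-192 had 1.67 against 0.49, but both of these lay below the detection limit at 17 dph, so that their differences are not measured on both sides. Of the 30 pairs with both probes above the limit at 17 dph, 2 had opposite signs, miR-203a with -0.12 for the second probe against 0.70 and miR-21 with 0.044 against -0.45. All of these are after quantile normalization.

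Among the PC-coded candidates 65 were higher and 33 lower at 29 dph, and among the PN-coded ones 10 were higher and 27 lower. Of the PC-coded probes 357 of 544 overlapped another by at least 14 nt, in 88 sets. A candidate explanation is that they target fragments of longer RNAs, for which a bound of over 5 sets that span more than 30 nt had been set. There were 5 such sets, the longest of 48 nt, which left the explanation undecided, and no PN-coded set exceeded 24 nt. The span cannot decide it, since probes that cover only a short part of a longer RNA would not pass the bound. The 5S rRNA control probes bright on both arrays had densities at 29 dph between 0.575 and 1.11 times those at 17 dph, while the median ratio of the 126 detected miRNAs was 2.23.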
